A study of Mus musculus with 6 samples.

How the data were processed

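Total RNA from fetal livers of mouse embryos at embryonic day 13.5 was measured on 6 Illumina bead arrays. Per the labels, 3 arrays held liver with both R26-LSL-KITD816V and Vav-iCre (double transgenic) and 3 held liver of single transgenic controls. Of the controls, 1 carried Vav-iCre and 2 carried R26-LSL-KITD816V. Groups, genotypes and replicate numbers came from the labels. Nothing in the labels says which embryo, litter or day a replicate number stands for, so p-values measure the spread between these samples, which may be technical in part. All 6 arrays sat on 1 chip, with the controls on the first 3 positions and the double transgenic livers on the last 3, so the position on the chip and the group cannot be told apart.

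The deposited table holds a signal intensity for each of 45281 probes and array, neither log transformed nor normalized between arrays, per the file headers and the values. It also holds a detection p-value per probe and array, deposited by the authors, which compares the probe with negative control beads. GenomeStudio is named in the submitters' processing notes, and its version is not given in the sources used here. The authors' deposited value table holds intensity values of the same probes. It differed from a quantile normalization of the deposited signal by at most 0.302% for any probe, so it is taken as quantile normalized on the linear scale. Its column medians were 141 on each array (log2 7.13 to 7.14). No background subtraction was seen in either table, and whether one was applied upstream stays unknown.

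Values were computed in R 4.3.3 with limma 3.58.1. The background was corrected with neqc, with negative controls inferred from the detection p-values and an offset of 16, followed by quantile normalization and log2. Probes were kept where the detection p was below 0.05 on at least 3 of the 6 arrays, which left 17855 probes. Gene symbols were updated through a RefSeq gene table of the GRCm38.p6 assembly: 27380 probes had a current symbol, 8359 were updated from an older symbol, 9524 kept the name in the file and 18 with several names were left out. Each gene was represented by the kept probe with the highest mean over the 6 arrays, which gave 12262 genes. Of these, 3907 had more than 1 kept probe. The files name no genome build, so no coordinates are given. All levels below are normalized log2 intensities, and changes are differences of their group means, double transgenic minus control.

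The groups were compared with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all 12262 genes and a threshold of adjusted p below 0.05. The 2 control genotypes were compared in a fit of 3 genotypes over all 6 arrays, in which the lone Vav-iCre control is assumed to vary like the other groups. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 26 lists with at least 4 measured members, with an estimated correlation and with fry as alternatives. For 28 lists the counts of members past the threshold are given over all genes and adjusted over the list alone. A gene not detected on any array of 1 group has only a bound there. It is given as "at least N-fold", from the mean of the detected group against the mean of, per array, the higher of the lowest detected signal and the gene's own value.

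The named genes followed a rule fixed before the data were examined. It took the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap, without predicted genes. It added Kit and Epor and, of each list, up to 4 members past the threshold by smallest adjusted p. Of the genes this rule takes, 1 is not reported here. The groups, the 28 lists and the tests of the report were also fixed before the data were examined, and the closing section names what was chosen later.

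The steps were tested on simulated data for the double transgenic comparison over 12262 genes, of which 200 were changed. At a change of 1 on the log2 scale, 27% of the changed genes were recovered, and at a change of 2, 94% were. A further list of 20 genes was shifted by 0.5. Of the 12042 genes left unchanged, 3 were called. The simulated noise was independent between genes and arrays, without the correlation between genes or the shared departure of replicate 1 seen in the real data. These rates therefore need not hold for the real arrays. The precision is limited by the number of arrays. Between 38.1% and 39.5% of probes were detected on each array at a detection p below 0.05, with a median signal of 137 to 144.

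Replicate numbers were checked for pairing, since the titles number both groups 1 to 3. Across genes, deviations from the group mean correlated between same-numbered arrays at 0.536 for number 1, 0.283 for number 2 and 0.206 for number 3. Each exceeded the limit of 0.1 set beforehand, so the numbers were used as a block in 1 of the alternatives, with the titles as their only source. The main comparison left them out. Of the 6 arrays, 4 correlated best with their own number. Control replicate 3 and double transgenic replicate 2 correlated at 0.371, and control replicate 2 and double transgenic replicate 3 at 0.197. Deviations from a group mean cancel within the group. A departure shared by number 1 alone therefore makes numbers 2 and 3 correlate however they are matched, and the pairing of numbers 2 and 3 is not shown.

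The alternatives were another background correction or none, median scaling, cyclic loess, the authors' value table, no filter and a stricter filter on dim probes, averaging or testing each probe, trend and robust moderation, array weights, the replicate number as a block, and leaving out each array in turn.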

Results

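Gene expression was measured in fetal livers of mouse embryos at embryonic day E13.5, when the liver is the main site of blood formation. In the double transgenic embryos, Cre recombinase made under the control of Vav, a gene active in blood cells, was combined with a KITD816V transgene in the ROSA26 locus. KIT is the receptor for stem cell factor, and D816V is a substitution in its kinase domain known to make the receptor active without its ligand. Each group had 3 arrays, and the labels do not say whether each held a separate liver. The controls carried only 1 of the transgenes, Vav-iCre on 1 array and R26-LSL-KITD816V on 2. Between 17249 and 17873 of 45281 probes were detected per array.

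In the double transgenic livers 24 of 25 liver epithelial genes, 11 of 24 monocyte and macrophage genes and 6 of 31 late erythroid genes fell, and 13 of 25 hypoxia response genes rose. As lists these shifts passed with a preset correlation between genes and did not with an estimated correlation (adjusted p = 0.411, 0.411, 0.677 and 0.411 in that order). With 6 arrays, camera with an estimated correlation has few residual degrees of freedom, so it can miss even a large shift. Among the largest falls was Saa4, a serum amyloid gene, which fell by 3.47 on the log2 scale (SE 0.35, n = 3 per group, adjusted p = 0.0014). Saa4 was detected on 2 of the 3 double transgenic arrays, so the size of its fall depends in part on values near the background. The largest rise was in Trib3, a pseudokinase induced by cell stress, at 3.65 (SE 0.39, adjusted p = 0.00147), from 7.09 ± 0.61 in controls to 10.74 ± 0.67 (SD, n = 3). Kept probes of Trib3 ranged from 2.57 to 3.65. Of 12262 genes tested, 1095 changed, 310 upward and 785 downward. Of these, 808 changed at least 2-fold, 161 upward and 647 downward, and 105 were predicted genes. Among the 1095 genes, 76 were not detected on any double transgenic array and 28 were not detected on any control array. These passed the filter through the other group alone, so their fitted folds depend on the background.

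In every one of the 1095 genes the values of the groups did not overlap. Such a separation held for 3492 genes (28.5%), against 10% by chance with 3 exchangeable arrays per group. Replicate 1 of both groups deviated together, so the share without a group change may differ from 10%. With the replicate number as a block, 1743 genes passed, 632 upward and 1111 downward, including 1089 of the 1095. The count fell to 555 without control replicate 2 (100 upward), 594 without control replicate 3 (107 upward) and 620 without double transgenic replicate 2 (132 upward), and to 735 without double transgenic replicate 3 (159 upward). It was 671 with a stricter filter on dim probes, 2749 with array weights (1238 upward and 1511 downward) and 1830 without replicate 1 of both groups (717 upward and 1113 downward), and the count of genes changed at least 2-fold was 347 without background correction.

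Genes of hepatoblasts and hepatocytes formed the group with the lowest median. Of 25 measured members 24 fell, none rose and 1 did not pass (25 fell adjusted over the list alone). Their median change was -2.03 (adjusted p = 4e-26 with the preset correlation, adjusted p = 0.411 with an estimated correlation). Apoh, a plasma glycoprotein, fell by 3.05 (SE 0.21). Vtn, which encodes vitronectin, changed by -2.53 (SE 0.27), Itih2, an inhibitor subunit of plasma, by -2.31 (SE 0.23) and Ahsg, the fetal plasma protein fetuin A, by -1.98 (SE 0.21). Serpina1e and Serpina1c, of the alpha-1 antitrypsin family, changed by -3.43 (SE 0.45) and -3.31 (SE 0.27). Their sequences are close to each other, so a probe can read more than 1 copy. The apolipoprotein gene Apof changed by -3.38 (SE 0.28), the carboxylesterase Ces3 by -3.43 (SE 0.33) and the carbonic anhydrase Car3 by -3.32 (SE 0.35). Other genes among the 10 largest falls were Timd2 (-3.32), Apol11b (-3.29) and Bcas1 (-3.29). Car3 was detected on 1 of the 3 double transgenic arrays, and Ces3 and Timd2 on 2. The sizes of these falls therefore depend in part on values near the background.

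Monocyte and macrophage genes fell in 11 of 24 members, 1 rose and 12 did not pass (13 fell and 1 rose adjusted over the list alone). The list's median was -0.95 (adjusted p = 3.85e-10, and adjusted p = 0.411 with an estimated correlation). Spic, a transcription factor of iron-recycling macrophages, fell by 2.67 (SE 0.18). Adgre1, a macrophage surface antigen, changed by -2.22 (SE 0.24), and Timd4, a receptor for dying cells, was 4.01-fold lower (SE 0.21 on the log2 scale). Timd4 was detected on 2 of the 3 double transgenic arrays, so its fold depends in part on values near the background. Dnase2a, a lysosomal nuclease with which macrophages digest expelled erythroid nuclei and which is also made in other cells, rose by 1.51 (SE 0.17). Kept probes of Spic ranged from -2.67 to -1.26.

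Among late erythroid membrane and maturation genes 6 of 31 fell, none rose and 25 did not pass (7 fell adjusted over the list alone). The median was -0.45 (adjusted p = 2.54e-05, and adjusted p = 0.677 with an estimated correlation), and -0.19 without double transgenic replicate 1 and -0.69 without double transgenic replicate 3. Xpo7, a nuclear export receptor used during erythroid nuclear condensation, fell by 2.62 (SE 0.30). Tmcc2 changed by -2.49 (SE 0.29), Fn3k, a kinase that removes sugar from proteins, by -2.38 (SE 0.28) and Bcl2l1, which encodes the survival protein BCL-XL, by -1.56 (SE 0.26). A second kept probe of Fn3k stood at -1.36. Of 20 genes of heme synthesis and iron uptake 2 fell and 18 did not pass, with a median of -0.30 (adjusted p = 0.0151, and adjusted p = 0.677 with an estimated correlation). They were Slc25a37, the mitochondrial iron importer, at -1.36 (SE 0.22), and Alas2, the first enzyme of erythroid heme synthesis, at -1.34 (SE 0.28). Without double transgenic replicate 1 the heme list's median was -0.12 (adjusted p = 0.265), and the Alas2 call was lost when any 1 of 3 arrays was left out (highest adjusted p = 0.0736) and with no filter on dim probes (adjusted p = 0.0588).

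Of 18 erythroid transcription factors and Epor, 1 rose, 3 fell and 14 did not pass (2 rose and 4 fell adjusted over the list alone), with a median of -0.01 (adjusted p = 0.785). E2f2 was at -1.09 (adjusted p = 0.0448), Tfdp2 at -0.78 (adjusted p = 0.0349), Tal1 at -0.65 (adjusted p = 0.0473) and Stat5a at 0.91 (adjusted p = 0.0478). Each of these calls was lost when certain single arrays were left out, and that of Tal1 when any 1 of the 6 was left out (highest adjusted p = 0.185). Median scaling ended the calls of E2f2 (adjusted p = 0.0648), Tfdp2 (adjusted p = 0.0782) and Tal1 (adjusted p = 0.126), and averaging probes ended those of E2f2 (adjusted p = 0.0658), Tfdp2 (adjusted p = 0.0517) and Stat5a (0.57, adjusted p = 0.121). E2f2 and Stat5a were also lost with no filter on dim probes (adjusted p = 0.110 and 0.0905) and with the stricter filter (adjusted p = 0.0517 and 0.0522), and Tal1 and Stat5a with every probe tested (adjusted p = 0.0551 and 0.0502). Stat5a was lost besides with cyclic loess (adjusted p = 0.0822) and with trend and robust moderation (adjusted p = 0.0521), and Tfdp2 and Stat5a without replicate 1 of both groups (adjusted p = 0.0622 and 0.0892). Kept probes ranged from -1.16 to -0.23 for E2f2 and from 0.24 to 0.91 for Stat5a. Epor, the erythropoietin receptor, stood at 0.15 (SE 0.20, adjusted p = 0.702).

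Of 3 embryonic globins, Hba-x rose by 1.35 (SE 0.24, adjusted p = 0.0102) and Hbb-bh1 by 1.04 (SE 0.21, adjusted p = 0.0175), and 1 did not pass, with a list median of 1.04. The call of Hbb-bh1 was lost when its probes, at 0.32 to 1.04, were averaged (0.68, adjusted p = 0.0636), and both calls without certain single arrays (adjusted p up to 0.0520 for Hba-x and 0.0878 for Hbb-bh1). None of 3 adult globins passed, with a median of -0.08. Both lists had fewer than 4 measured members and were not tested as lists. Hba-a1, Hbb-b1 and Hbb-y, at means of 14.94, 14.95 and 14.88, lay near the brightest possible value of 15.27, which limits any rise that can be seen in them. A fall may be flattened there as well, so the adult globins are not shown to be unchanged. Slc4a1 and Eraf of the late erythroid list, which did not pass, lay near it too, at 14.74 and 14.98. As means over all arrays, Hba-x at 14.13, Hbb-bh1 at 13.74 and Hbb-b2 at 12.26 lay further below. In the double transgenic livers alone Hba-x stood at 14.81 and Hbb-bh1 at 14.26, so the rise of Hba-x may be limited in the same way.

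**Figure D1:**
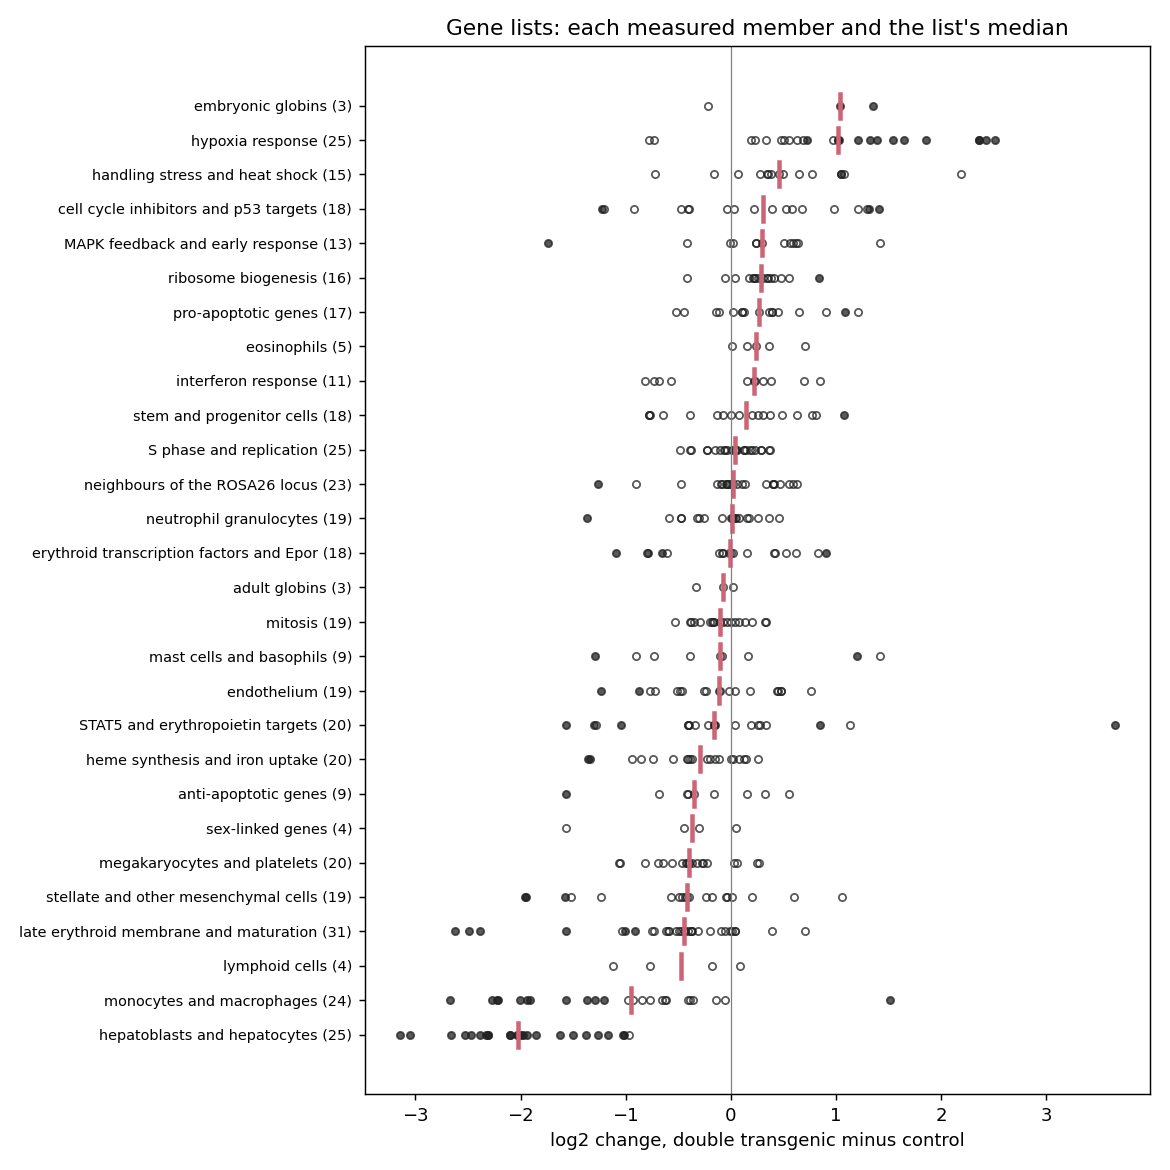
Log2 change of each measured member of the 28 gene lists, double transgenic minus control (x axis), with members past an adjusted p of 0.05 filled and the others open; red bars mark list medians and the number after each list is its measured members. The hepatoblast and hepatocyte median lies at -2.03 and the hypoxia response median at 1.02.

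Genes of the hypoxia response rose in 13 of 25 members, none fell and 12 did not pass (17 rose and 2 fell adjusted over the list alone). Their median was 1.02 (adjusted p = 3.54e-09, and adjusted p = 0.411 with an estimated correlation). Ankrd37 rose by 2.51 (SE 0.32), Egln3, an oxygen-sensing prolyl hydroxylase, by 2.42 (SE 0.37), and the glycolytic enzymes Pfkp and Aldoa by 2.35 (SE 0.25) and 1.85 (SE 0.24). Handling stress and heat shock genes, a list of technical states, had a median of 0.46 in the same direction (adjusted p = 0.0182, and adjusted p = 0.677 with an estimated correlation). Of its 15 members Junb, an immediate early transcription factor, rose by 1.05 (SE 0.20, adjusted p up to 0.0565 without single arrays) and 14 did not pass (2 rose adjusted over the list alone). Without double transgenic replicate 3 the stress list's median was 0.30 (adjusted p = 0.0744).

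The other large rises were Esm1, a secreted proteoglycan of endothelium, at 3.59 (SE 0.40), Chac1, a glutathione-degrading enzyme, at 2.74 (SE 0.42), and Slc7a3, a cationic amino acid transporter, at 2.38 (SE 0.26). They also included Mapt, the microtubule protein tau, at 2.58 (SE 0.34), the cytokine Il4 at 2.53 (SE 0.30) and Sapcd1 at 2.43 (SE 0.37). Mapt and Il4 were each detected on 1 of the 3 control arrays, so the sizes of their rises depend in part on values near the background. Tmem184a, not detected on any control array, was at least 4.50-fold higher (adjusted p = 0.0346), a call lost without most single arrays. Its fitted difference was 1.89 without double transgenic replicate 2 and 3.37 without double transgenic replicate 3. It was also lost with a normexp offset of 50 (1.68, adjusted p = 0.0536), without background correction and in the authors' value table (1.17, adjusted p = 0.107), with no filter on dim probes and without replicate 1 of both groups (adjusted p = 0.133 each). A second kept probe stood at 0.30 for Slc7a3 and at 0.96 for Tmem184a.

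Kit itself stood at 9.21 ± 0.29 in controls and 9.98 ± 0.31 in double transgenic livers (SD, n = 3), a difference of 0.77 (SE 0.23) that did not pass (adjusted p = 0.0816). The levels were 8.87, 9.32 and 9.42 in control replicates 1 to 3 and 10.19, 10.11 and 9.63 in double transgenic replicates 1 to 3. With median scaling (0.90, adjusted p = 0.0473) or array weights (0.63, adjusted p = 0.0355) it passed. A second kept probe stood at 0.33. Whether the probe lies in the transgene is unknown, so it may check nothing about the labels. Of 18 stem and progenitor genes Gata2, a transcription factor of early progenitors, rose by 1.07 (SE 0.19, adjusted p = 0.0105, up to 0.0553 without single arrays), and 17 did not pass, with a median of 0.14 (adjusted p = 0.643).

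**Figure D2:**
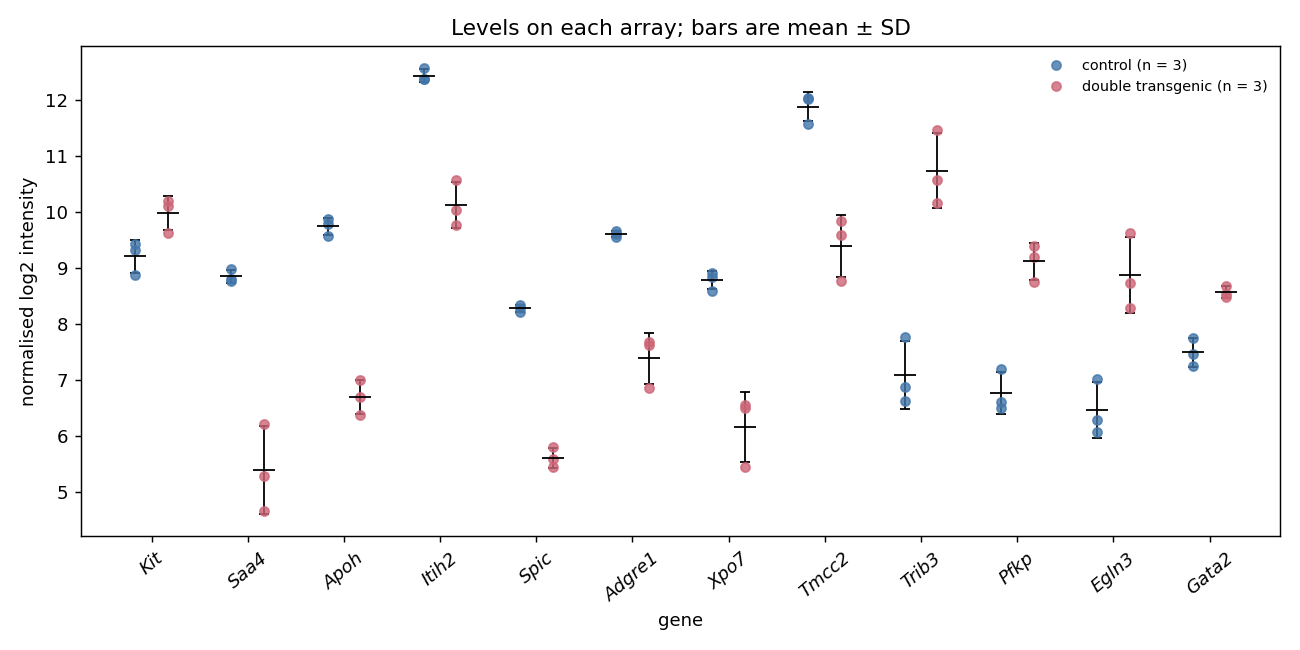
Normalised log2 intensity (y axis) of 12 genes on each array, with controls in blue and double transgenic livers in red and black bars giving mean ± SD of 3 arrays. Spic falls from 8.28 to 5.60 and Trib3 rises from 7.09 to 10.74. The groups overlap in no gene shown, but all except Kit were taken from genes past the threshold, none of which overlapped.

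The 20 targets of STAT5 and erythropoietin, which need not report on KIT alone, went both ways, with 2 rises and 3 falls (2 and 4 adjusted over the list alone) and 15 that did not pass. Their median was -0.16 (adjusted p = 0.45), with -0.24 without double transgenic replicate 3, -0.03 without double transgenic replicate 1 and 0.04 with the stricter filter. The rises were Trib3, which the closing section also counts among amino acid response genes, and Ccnd2, a G1 cyclin, at 0.84 (SE 0.17). The falls were Bcl2l1, Socs3, a feedback inhibitor of cytokine signalling, at -1.31 (SE 0.32), and Cish at -1.05, named after its value was seen. Of 13 MAPK feedback and early response genes, Ccnd1, another G1 cyclin, fell by 1.74 (SE 0.27) and 12 did not pass (2 rose and 1 fell adjusted over the list alone), with a median of 0.29 (adjusted p = 0.33), 0.19 without double transgenic replicate 3 and 0.52 without double transgenic replicate 1. Of 9 mast cell and basophil genes, Cpa3, a mast cell protease, was at -1.29 (adjusted p = 0.0362) and Prss34, a basophil protease not detected in controls, was at least 1.84-fold higher (adjusted p = 0.0353). The mast cell list had 7 members not past and a median of -0.11 (adjusted p = 0.682, -0.32 without double transgenic replicate 3 and 0.01 without double transgenic replicate 2), with 2 rising and 1 falling adjusted over the list alone. The calls of Socs3, Cpa3, Prss34 and Ccnd2 were lost without single arrays, with adjusted p up to 0.138, 0.115, 0.130 and 0.0904. Without background correction and in the authors' value table the calls of Socs3 (-0.71, adjusted p = 0.0521), Cpa3 (-0.59, adjusted p of at least 0.0622) and Prss34 (0.41, adjusted p of at least 0.0928) were lost. With no filter on dim probes they were lost as well (adjusted p = 0.112, 0.105 and 0.0952), that of Prss34 also with a normexp offset of 50 (0.67, adjusted p = 0.0529) and that of Socs3 without replicate 1 of both groups (adjusted p = 0.106). Kept probes of Cpa3 ranged from -1.52 to -0.46.

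Of 17 pro-apoptotic genes Diablo, an inhibitor of caspase inhibitors, rose by 1.09 (SE 0.26, adjusted p = 0.0362) and 16 did not pass (4 rose adjusted over the list alone), with a median of 0.26 (adjusted p = 0.129). Of 9 anti-apoptotic genes Bcl2l1 fell and 8 did not pass, with a median of -0.35 (adjusted p = 0.351), or -0.10 without double transgenic replicate 2. Bcl2l1 is a member of 3 lists. None of 25 S phase genes (median 0.04, adjusted p = 0.967) and none of 19 mitosis genes (median -0.10, adjusted p = 0.427) passed. Of 18 cell cycle inhibitors and p53 targets 2 rose, 1 fell and 15 did not pass (5 and 2 adjusted over the list alone), with a median of 0.30 (adjusted p = 0.406), or 0.14 without double transgenic replicate 1 and 0.46 without double transgenic replicate 2. Cdkn2b, not detected in controls, was at least 2.04-fold higher (adjusted p = 0.0029), Sesn2 was at 1.31 (adjusted p = 0.0197) and Cdkn2d at -1.23 (adjusted p = 0.0123). Noc2l alone of 16 ribosome biogenesis genes rose, by 0.84 (SE 0.17), and 15 did not pass. That list's median of 0.28 did not pass (adjusted p = 0.0897) but did with the replicate number as a block (adjusted p = 0.0450), without background correction and in the authors' value table (0.23, adjusted p up to 0.0441), with no filter on dim probes (adjusted p = 0.00738), with every probe tested (adjusted p = 0.0323) and without double transgenic replicate 3 (0.36, adjusted p = 0.0181). It did not with an estimated correlation (adjusted p = 0.677, and adjusted p = 0.808 with the block). The calls of Diablo, Noc2l, Sesn2 and Cdkn2d were lost when certain single arrays were left out, with adjusted p up to 0.130, 0.102, 0.0675 and 0.0595. That of Diablo was also lost with no filter on dim probes (adjusted p = 0.0875) and without replicate 1 of both groups (0.75, adjusted p = 0.0571). That of Sesn2 was lost without background correction and in the authors' value table (0.53, adjusted p of at least 0.0635) and with no filter on dim probes (adjusted p = 0.0593).

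Among markers of other cells, none of 20 megakaryocyte and platelet genes passed. Their median of -0.40 passed as a list (adjusted p = 0.0244, and adjusted p = 0.798 with an estimated correlation), but not without control replicate 1, control replicate 3 or double transgenic replicate 2 (highest adjusted p = 0.278, median -0.17 without double transgenic replicate 2). Of 19 stellate and other mesenchymal genes 3 fell and 16 did not pass, with a median of -0.42 (adjusted p = 0.0244, and adjusted p = 0.798 with an estimated correlation). That call was lost without control replicate 1, double transgenic replicate 2 or double transgenic replicate 3 (median -0.14 without control replicate 1). Kitl, the ligand of KIT, was not detected in double transgenic livers and was at least 2.24-fold higher in controls (adjusted p = 0.00233). Reln fell by 1.95 (SE 0.27), with a second kept probe at -0.64, and the chemokine Cxcl12 stood at -1.96 (SE 0.48, adjusted p = 0.039, up to 0.137 without single arrays). The Cxcl12 call was also lost without background correction and in the authors' value table (-1.74, adjusted p of at least 0.0542) and with no filter on dim probes (adjusted p = 0.138).

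Of 19 endothelial genes Gpr182 (-1.24) and Lyve1 (-0.88), both made in liver sinusoids, fell and 17 did not pass, with a list median of -0.12 (adjusted p = 0.33) that passed at -0.25 without double transgenic replicate 3 (adjusted p = 0.0399), but not over all arrays with an estimated correlation (adjusted p = 0.877). Both calls were lost when certain single arrays were left out (adjusted p up to 0.0951 for Gpr182 and 0.0976 for Lyve1), that of Lyve1 also with median scaling (adjusted p = 0.0665) and that of Gpr182 with no filter on dim probes (adjusted p = 0.0667). Of 19 neutrophil genes Cebpa, a transcription factor shared with hepatocytes, was not detected in double transgenic livers and was at least 2.13-fold higher in controls (adjusted p = 0.00337). The other 18 did not pass, with a median of 0.01 (adjusted p = 0.476) that passed at -0.24 without double transgenic replicate 3 (adjusted p = 0.00791) and stood at 0.25 without double transgenic replicate 2. With an estimated correlation over all arrays it did not pass (adjusted p = 0.917). No member passed among 5 eosinophil genes (median 0.24, adjusted p = 0.714), 4 lymphoid genes (median -0.47, adjusted p = 0.255, 1 fell adjusted over the list alone) or 11 interferon response genes (median 0.21, adjusted p = 0.967). The eosinophil median ran from -0.35 without control replicate 1 to 0.76 without control replicate 3, the interferon median from 0.03 to 0.46 without double transgenic replicate 3 and replicate 1, and the lymphoid median passed at -0.76 with every probe tested (adjusted p = 0.0172). Without single arrays it ran from -0.69 to -0.28, and it did not pass with an estimated correlation (adjusted p = 0.677). Of 23 neighbours of the ROSA26 locus Il17rc fell by 1.26 (SE 0.24, adjusted p up to 0.0643 without single arrays) and 22 did not pass, with a median of 0.02 (adjusted p = 0.785). Il17rc was detected on 2 of the 3 double transgenic arrays. For lists with no such count given, the counts were the same adjusted over the list alone.

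The 4 Y-linked genes did not pass (median -0.37, adjusted p = 0.476, and 0.49 without double transgenic replicate 2). Eif2s3y stood at 10.55, 10.04 and 9.82 in control replicates 1 to 3 and at 10.54, 4.54 and 10.61 in double transgenic replicates 1 to 3. Ddx3y stood at 10.38, 10.17 and 10.22 in the controls and 10.93, 8.27 and 10.65 in the double transgenic livers, and Kdm5d at 6.35, 6.61 and 5.87 against 7.19, 4.52 and 7.25. Uty stood at 5.82, 5.85 and 5.87 against 5.53, 4.79 and 5.88. Double transgenic replicate 2 had the lowest value of each. The labels give no sex. Y-linked RNA was seen in all controls and was low in double transgenic replicate 2 alone, though Ddx3y still stood at 8.27 there. The groups therefore appear unbalanced for sex, which was not a term of the comparison. With the replicate number as a block, the number of falling genes went from 2 to 4 in the heme list, from 0 to 3 in the megakaryocyte list, from 3 to 5 in the stellate list and from 2 to 4 in the endothelial list. Rises and falls went from 1 and 3 to 3 and 5 among erythroid transcription factors and from 2 and 1 to 5 and 3 among cell cycle inhibitors and p53 targets, and falls from 0 to 2 among lymphoid genes. In each other list the counts of rises and of falls moved by at most 3.

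**Figure D3:**
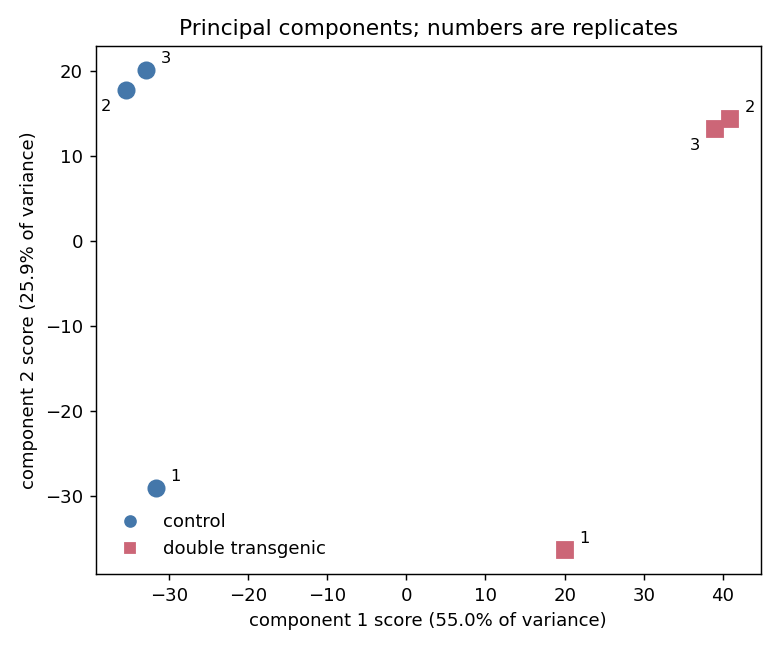
Scores of the 6 arrays on the first 2 principal components of the tested genes (x axis, component 1, 55.0% of variance; y axis, component 2, 25.9%), with controls as blue circles and double transgenic livers as red squares, numbered by replicate. Component 1 parts the groups, with controls from -35.4 to -31.6 and double transgenic livers above 0 and up to 40.9, and replicate 1 of each group has the lowest score on component 2.

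The controls held 2 genotypes, which raises the question whether they differed from each other. No gene passed between the Vav-iCre control and the 2 R26-LSL-KITD816V controls in the limma fit (lowest adjusted p = 0.507). At an unadjusted p below 0.05 there were 1191 genes (9.71%), of which 99 were among the 1095 genes of the main comparison. Trib3 differed by 1.02 (adjusted p = 0.510), Spic by -0.09 (adjusted p = 0.888) and Kit by -0.50 (adjusted p = 0.548), Vav-iCre minus R26-LSL-KITD816V. With 1 array against 2, differences of this size cannot be told from the spread, and replicate number 1 and the Vav-iCre genotype coincide among the controls.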

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

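The alternatives without replicate 1 of both groups and with the block and an estimated correlation together were chosen after seeing the data. The count of 1095 genes was 671 with the stricter filter (9018 genes tested), 2749 with array weights, 1743 with the replicate block and 1830 without replicate 1 of both groups. It ran from 555 (without control replicate 2) to 1395 (without double transgenic replicate 1) when single arrays were left out. The count of 808 genes changed at least 2-fold was 521 with normexp and an offset of 50, 347 without background correction and with the authors' value table, and 466 with the stricter filter. Uncorrected background adds to both groups and shrinks folds, and the stricter filter tests fewer genes. The cause was not tested for the others. The controls' 2 genotypes gave 0 genes in every setting run.

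The estimated correlation ended all 8 list calls, with medians as before: hepatoblasts -2.03, macrophages -0.95 and hypoxia 1.02 (adjusted p = 0.411), late erythroid -0.45, heme -0.30 and stress 0.46 (adjusted p = 0.677), megakaryocytes -0.40 and stellate -0.42 (adjusted p = 0.798). With the block and an estimated correlation adjusted p was 0.780 for all 8. Under fry, hepatoblasts, macrophages and hypoxia kept their calls, and late erythroid (adjusted p = 0.220), heme (adjusted p = 0.258), stress (adjusted p = 0.196), megakaryocytes (adjusted p = 0.435) and stellate (adjusted p = 0.384) lost theirs. The pro-apoptotic list passed at 0.26 with no filter (adjusted p = 0.0148) and at 0.30 with every probe tested (adjusted p = 0.0408), but not with an estimated correlation (adjusted p = 0.677). The stress list was at 0.35 with the stricter filter (adjusted p = 0.172), and the heme list at -0.26 without replicate 1 of both groups (adjusted p = 0.0625). Adult globins were at -0.026 with median scaling, -0.17 with cyclic loess and -0.036 with every probe tested. Leaving out single arrays gave -0.097 to 0.022 for adult globins, 0.30 to 0.57 for stress, -0.41 to -0.12 for heme, -0.69 to -0.19 for late erythroid genes (call kept), -0.58 to -0.17 for megakaryocytes and -0.63 to -0.14 for stellate genes. Among lists that did not pass it gave -0.08 to 0.11 for erythroid transcription factors and Epor, 0.07 to 0.22 for stem and progenitor genes, 0.16 to 0.35 for pro-apoptotic genes, -0.19 to -0.04 for mitosis, -0.0038 to 0.09 for S phase, -0.27 to -0.06 for endothelium and 0.02 to 0.13 for neighbours of the ROSA26 locus. The cause was not tested.

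Of 61 named calls, 39 held without each single array, 22 were lost when at least 1 of the arrays was left out, and 1 of these, Tal1, whichever array was left out. Over 1178 values of named genes across settings, 1050 kept direction and side of the threshold, 126 lost the call, 2 gained one and 0 reversed. The replicate block changed no call of a named gene, and of the lists it changed only that of ribosome biogenesis.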

Other observations

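Apart from the splits of the arrays, the tests here, the intensity trend included, and the list of amino acid response genes were chosen after the patterns they address were seen. The values measured by the tests of the scaling of hepatic genes, the genotype of control replicate 1, the immediate early genes and the hepatic share had also been seen by then, and the neighbour count among group-changed genes was added after that of the departing genes. Trib3, Chac1 and Slc7a3 belong to the ATF4 and amino acid response, which cells raise when amino acids run short or proteins misfold. Of 34 measured members of a list of such genes, written after 7 of them had been seen among the rises, 10 rose and 1 fell, the 7 included. Of the 27 members not seen before, 3 rose, 1 fell and the others did not pass. The transcription factor Ddit3 rose by 1.49 (SE 0.29), the proline synthesis enzyme Pycr1 by 1.23 (SE 0.17) and the translation inhibitor Eif4ebp1 by 0.97 (SE 0.17). Gpt2 fell by 1.08 (SE 0.18). Atf4 itself stood at 0.20 (SE 0.23, adjusted p = 0.666). A hypothesis is that ATF4 activity may be higher in these livers. The 27 members had a median of 0.53, with 24 above 0, and none of 100000 random sets of tested genes reached it (permutation p = 1e-05, one-sided, the smallest these can give). Genes are not independent replicates, so this p overstates the evidence.

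Replicate 1 of both groups departed together. In each group replicate 1 differed from the mean of replicates 2 and 3 by over 1 on the log2 scale and in the same direction at 142 genes. Of these, 77 were higher and 65 lower, and a further 5 genes departed in opposite directions. Without a test, the median difference of replicate 1 was 0.53 in the control and 1.02 in the double transgenic liver over 19 stellate and other mesenchymal genes, and -2.14 and -0.96 over 5 eosinophil genes. Among single genes Mfap4, a matrix protein gene, differed by 1.76 and 1.79, Lum by 1.40 and 2.24 and Ear3, an eosinophil ribonuclease, by -2.87 and -1.74. Ccnb1ip1 differed by -3.06 and -3.27. These genes were named after their values were seen.

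The departures of both groups correlated across genes at 0.536, which is the pattern itself and so decides nothing about the Vav-iCre genotype of control replicate 1. What this genotype adds to the departure of that array stays open. An intensity trend of the arrays is not its whole cause, since the correlation was 0.539 after cyclic loess and removal of a smooth trend. Alleles of the mixed C57/Bl6 and 129Sv background, shared by litter mates, may account for genes such as Ccnb1ip1. Such genes would neighbour each other, and 11 pairs lay within 10 genes against a median of 6 in random sets (one-sided permutation p = 0.0249). The genes with the smallest p between the groups also gave 11 pairs (permutation p = 0.0257), so the count does not single out alleles, and litter, dissection and allele differences stay open.

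The fall of hepatic genes is not made by the scaling between arrays, since the list's highest median over 5 other scalings and background corrections was -1.89. Among these only median scaling and cyclic loess replace the quantile normalization, and both gave a median no higher than that. Whether there may be fewer liver epithelial cells or a less mature epithelium was tested by setting late hepatocyte genes against early hepatoblast genes at control levels of at least 8. The late genes stood -0.66 apart from the early ones in median (permutation p = 0.213, two-sided), but only 2 late and 10 early genes were bright enough. Over all 14 late and 15 early genes measured the medians were -1.45 and -1.28, which lie closer together, though with the dimmer genes included, whose falls are limited by the background. The explanations therefore cannot be told apart.

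The rise of hypoxia response genes may come from handling before lysis or from low oxygen in the embryo, for which no test was made. Of 7 immediate early genes 1 passed and the median was 0.77, which leaves handling open. A lower share of hepatic RNA would lift all other transcripts alike. The normalization would take out most of such a common lift, so only a gap between lists can bear on it. The median was -0.091, with quartiles of -0.41 and 0.12, over 93 late erythroid, progenitor, S phase and mitosis genes. It was 1.02 over the hypoxia genes. The late erythroid genes fell as a list (-0.45), but the progenitor, S phase and mitosis medians of 0.14, 0.04 and -0.10 also lay below 1.02. This gap argues against a lift alike as the whole cause. Position on the chip is confounded with the group.

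The 6 arrays allow 10 splits into 3 and 3, too few for a share below 0.05. Of these splits 1, the real one, gave 1095 genes past the threshold and the highest other gave 0. For genes changed at least 2-fold 1 split, the real one, gave 808 and the highest other 0. For gene lists, 7 of the 10 splits gave as many as the real 8 of 26, and the highest other gave 15. If the replicate numbers pair the arrays, which is not shown beyond number 1, the real split compares with the 3 others that part all pairs. Those gave 0 genes each and at most 11 lists, and the rest keep some pairs together. Counts of list calls at the preset correlation therefore do not set the real split apart. Every other split mixes arrays of both groups, so part of the group difference stays in it and the rest widens its spread. The other splits therefore give no null for the lists, and their 0 genes do not by themselves tell against chance.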
